A study of Mus musculus with 64 samples.

How the data were processed

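Livers of male C57BL/6J mice were labelled by condition (4 °C or 25 °C) and hour (0, 6, 12 or 24), with 4 RNA libraries in each of 8 groups. The labels number the libraries 1 to 4 within a group and do not say that they came from separate animals, so p-values measure the spread between these samples, which may in part be technical. The 32 samples from chromatin immunoprecipitation, which are lanes of libraries from 2 replicates for 3 targets and input in 2 conditions, had no file here and are not analysed here.

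Per the labels' protocols, RNA was prepared with a stranded mRNA kit and sequenced on a NovaSeq as paired reads, reads were trimmed with skewer and aligned with STAR, genes at or near 0 were removed, and the authors normalized by trimmed means of M-values and tested with edgeR's generalized linear model. Per the file headers, however, the deposited tables have the columns of a DESeq2 results table: the mean normalized count, the log2 fold change, its standard error, a Wald statistic, a p-value and an adjusted p. Both statements are given as found; which tool made the tables is not settled by the sources used here. The genome build, the gene annotation, the read counter and all versions for the RNA data are not given in the sources used here.

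The deposited tables give a signal column, which per the file headers is a mean of counts divided by size factors over all libraries. It is identical in the 3 tables, and 1 value per gene, so it carries no error. Its sum is 23110339, and CPM means a gene's value scaled so that all genes sum to 1000000; 2 CPM (1 on the log2 scale) is a mean normalized count of 46.2, reached by 10546 genes. Depth per library is unknown from these tables. The deposited log2 fold changes and standard errors are model coefficients of the authors. The deposited score column is the Wald statistic and equals the fold change over its standard error in every row, within 4.09e-14. The deposited p-values equal the two-sided normal p of that score, and the adjusted p equals a Benjamini-Hochberg adjustment over the rows where it is given, both checked. An adjusted p was given for 13084 genes at 6 h and for 14618 at 12 h and at 24 h, with a lowest mean normalized count of 14.9, 7.47 and 7.47. A p was missing for 16 genes. Each sentence with an adjusted p of a single gene and its term refers to these values of the authors.

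The table names give the cold condition combined with a time. That the values are a condition-by-time term with room temperature and 0 h as references was checked on 1750 genes with a mean normalized count under 0.1, whose reads come from 1 or few libraries. Such a term predicts 8 sign patterns over the 3 tables, 1 for each group that could hold the reads, and 8 were found, each with 71 or more genes. Signs were read as departures from each table's most frequent value among these genes. A gene with reads in 0 h room temperature libraries alone, for example, lies above that value in all 3 tables (255 genes). The 8 patterns do not cover all of the 1750 genes. Other patterns were not counted, so the check could not show genes that go against such a term.

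The tests fixed before the data were examined assumed counts or normalized values per library and named a fallback for tables of comparisons. The fallback was used: calls are the authors' adjusted p under 0.05. Contrasts of cold with room temperature within 1 time were fixed as results but cannot be formed from these tables, since the 0 h difference is not in them.

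Differences between times were tested with the 2 terms' difference over the root of the sum of their squared standard errors, a two-sided normal p and Benjamini-Hochberg adjustment over genes with an adjusted p at both times. The terms share the 0 h groups, so their covariance is positive and this standard error is an upper bound. A covariance of 0.5 of the mean variance, which holds if the 4 groups vary alike, was added after the data were seen.

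Gene lists (41, with their members, fixed before the data were examined) were tested by the median log2 fold change of the members with an adjusted p, as a percentile among 10000 random lists of the same size drawn from the same expression deciles. The p is two-sided, the smallest it can be is 0.0002, and Benjamini-Hochberg adjustment ran over 106 tests; lists with fewer than 5 tested members had no test (7 lists at 1 or more times). Differences of lists between times were tested alike over 104 tests, which were added after the data were seen. Since no values per library are given, the correlation between members could not be estimated. For 3 lists, the median difference between times was also set against medians drawn from the members' own standard errors as independent, and against the median standard error, which holds where members vary as one; both took a covariance of 0 between the terms and were added after the data were seen.

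Gene symbols came from a table pairing Ensembl IDs with symbols, which matched 26280 of 26396 IDs; list names not found were matched through synonyms in a RefSeq table of assembly GRCm38.p6. Genes named in the text followed a rule fixed before the data were examined. At each time it takes the 10 largest rises and the 10 largest falls among genes past the threshold with at least 2 CPM and a symbol that is not a predicted gene, clone or pseudogene. It adds up to 4 members of each list with the smallest adjusted p, and genes of the study's question, among them Hnf4a, Ppara, Elovl3, Elovl6, Pex11a, Cpt1a, Fgf21, Cyp7a1, Cyp7b1, Cirbp and Rbm3. Some genes that the rule takes are not reported here. Genes outside the rule are marked as chosen after their values were seen.

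The procedure was tested on simulated tables with the real standard errors of 13084 genes, shared 0 h noise and 200 changed genes at 24 h. Of 100 genes changed by 1 on the log2 scale, 64 were recovered in the 24 h term, and 40 in the 24 h minus 6 h difference with 0 covariance. Of 100 changed by 2, 92 and 78 were recovered, all with the right sign; 11 and 0 unchanged genes were called. With 0.5 of the mean variance as covariance the difference recovered 68 and 94 and called 7 unchanged genes. Of 200 unchanged random lists, 13 had a p under 0.05. The simulated noise was independent between genes, so this does not show how lists whose members vary together behave.

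Alternatives covered the threshold (0.01 and 0.1), a fold change minimum (1 on the log2 scale), low and predicted genes, Benjamini-Yekutieli and Bonferroni adjustment, the list statistic and the random lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.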

Results

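RNA was sequenced from the livers of male C57BL/6J mice, an inbred laboratory strain, aged 3 months. The labels place the animals at 4 °C (cold) or at 25 °C (room temperature) and give the times 0, 6, 12 and 24 h. The 32 RNA libraries form 8 groups of 4 libraries each. The series title names the question: how the nuclear receptor HNF4A acts on peroxisome formation and fatty acid elongation in the liver during the heat-producing response to cold. A further 32 samples from chromatin immunoprecipitation (HNF4A, acetylated histone H3K27, RNA polymerase II and input) are not analysed here.

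The RNA data used are 3 tables of the authors' own comparisons for 26396 genes, 1 table each for 6, 12 and 24 h. Each holds the term by which the cold against room temperature difference at that time departs from the same difference at 0 h, on a log2 scale. A gene that "rose" or "fell" below did so in this term at an adjusted p under 0.05, so the change is measured against both room temperature and the 0 h groups. The cold against room temperature difference at a single time, 0 h included, is not given by these tables. They hold no values per library; the mean normalized counts sum to 23110339 per average library, of which the mitochondrial ribosomal RNA mt-Rnr2, named after its values were seen, takes 23.8%. No coordinates are printed, since the genome build is not given in the sources used here.

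After 6 h, the clock activators Arntl and Clock, Hnf4a and the fatty acid elongase Elovl3 rose, as did 9 of 16 genes of the male-biased and growth hormone list. The growth hormone feedback inhibitors Cish and Socs2, the peroxisomal thioesterases Acot3 and Acot4 and 6 of 24 cholesterol synthesis genes fell. In the authors' deposited table for 6 h, 920 of 13084 genes with an adjusted p changed, 509 up and 411 down. Of these, 345 changed at least 2-fold, 144 up and 201 down.

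**Figure D1:**
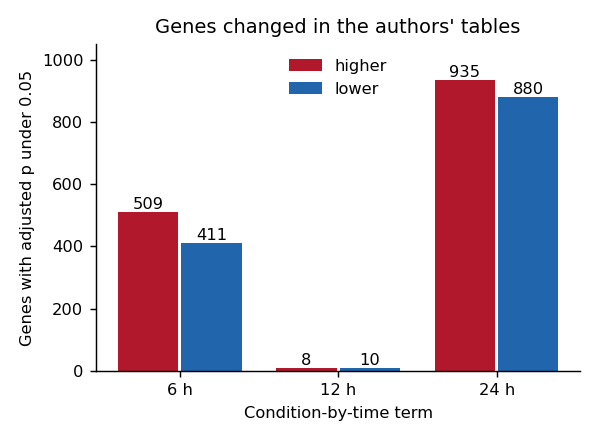
Number of genes with an adjusted p under 0.05 in the authors' deposited tables (vertical axis) for the condition-by-time term at 6, 12 and 24 h (horizontal axis), split into genes with a positive term (higher, red) and a negative term (lower, blue). At 12 h 8 genes were positive and 10 negative, against 509 and 411 at 6 h and 935 and 880 at 24 h.

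Hnf4a (ENSMUSG00000017950), which encodes the nuclear receptor named in the series title, rose at 6 h by a log2 fold change of 0.78 ± 0.13 (SE; adjusted p = 4.21e-06) in the authors' deposited table. Among the 17 tested liver transcription factors it was the 1 member that rose, while 4 fell (1 and 4 adjusted over the list alone). In the authors' deposited table the forkhead factors Foxa2 (-1.53 ± 0.33) and Foxa1 (-0.81 ± 0.24) and the cut-domain factor Onecut1 (-3.78 ± 1.14) fell. Of 25 tested genes known as HNF4A targets, 0 rose and 1 fell, both over all genes and adjusted over the list alone. That gene was Slc10a1, the bile acid importer (-0.83 ± 0.23 in the authors' deposited table). The targets' median of -0.08 lay below that of random lists (adjusted p = 0.0485), a call lost with the mean Wald statistic and with random lists not matched on expression.

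Elovl3 (ENSMUSG00000038754), an elongase of very long saturated and monounsaturated fatty acids, rose by 2.77 ± 0.42 at 6 h (adjusted p = 5.48e-08) in the authors' deposited table. It was the 1 member of 11 tested elongation genes to change over all genes; adjusted over the list alone, 1 rose and 2 fell. Elovl6, which elongates palmitate, had -1.33 ± 0.62 in the authors' deposited table and did not pass (adjusted p = 0.182). The list's median of -0.11 did not stand apart from random lists (adjusted p = 0.217).

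Of 16 tested peroxins, the proteins that build peroxisomes, 0 rose and 1 fell at 6 h, over all genes and adjusted over the list alone. Pex11g fell (-0.80 ± 0.21), and Pex11a, which promotes peroxisome division, had 0.41 ± 0.27 (adjusted p = 0.401) in the authors' deposited table. Among 26 peroxisomal beta-oxidation and matrix genes, 0 rose and 5 fell (1 and 5 adjusted over the list alone). Acot3 (-5.88 ± 0.86), Acot4 (-1.97 ± 0.37), the fatty acyl transporter Abcd2 (-3.29 ± 0.83) and the alpha-oxidation lyase Hacl1 (-1.11 ± 0.29) fell in the authors' deposited table. This list's median (0.10) and mean (-0.44) differ in sign, and the median did not stand apart from random lists (adjusted p = 0.754).

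Genes of the male-biased and growth hormone list had a median of 1.23 at 6 h, above random lists of matched expression (adjusted p = 0.000964). Of 16 tested members, 9 rose and 2 fell (11 and 3 adjusted over the list alone). Beside Elovl3, the major urinary protein genes Mup7 (3.63 ± 0.71) and Mup1 (3.58 ± 0.77) rose and Cish (-5.84 ± 0.96) fell in the authors' deposited table. The oxysterol hydroxylase Cyp7b1 (2.07 ± 0.50), Mup14 (3.58 ± 0.72), the selenium-binding Selenbp2 (4.43 ± 1.24) and the serpin Serpina1e (3.33 ± 0.84) also rose in the authors' deposited table, and Socs2 (-3.27 ± 0.87) fell. Among genes higher in female liver, Cyp2b9 (-6.13 ± 1.77) and Acot3 fell at 6 h in the authors' deposited table; 3 members were tested there, too few for a list test, and 0 rose and 3 fell adjusted over the list alone. The Mup, Cyp2 and Serpina1 families hold near-identical genes between which reads can be split, so the values of single members are uncertain.

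Clock genes moved in both directions at 6 h. In the authors' deposited table Arntl (2.56 ± 0.36), Clock (1.07 ± 0.18) and the repressor Nfil3 (2.10 ± 0.36) rose, and the repressor Bhlhe41 fell (-2.12 ± 0.57). Of 18 tested members, 4 rose and 3 fell (4 and 5 adjusted over the list alone). The median of -0.43 lay below random lists (adjusted p = 0.000964), whereas the mean Wald statistic of 0.05 had the opposite sign and did not pass (adjusted p = 0.916).

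Glucocorticoid-responsive genes had a median of 1.15 at 6 h (adjusted p = 0.000964). Of 15 tested, 8 rose and 0 fell (10 and 0 adjusted over the list alone). The cell cycle inhibitor Cdkn1a (3.06 ± 0.67), the kinase Sgk1 (1.02 ± 0.28), the growth factor binding protein Igfbp1 (3.09 ± 0.87) and the metallothionein Mt2 (3.05 ± 0.87) rose in the authors' deposited table. Heat shock genes had a median of 0.51 (adjusted p = 0.00163), with 3 of 13 up and 0 down, also adjusted over the list alone. The co-chaperones Dnaja1 (0.54 ± 0.16) and Bag3 (0.68 ± 0.22) and the chaperone Hsp90aa1 (0.67 ± 0.22) rose in the authors' deposited table. Of 18 genes of amino acid breakdown and the urea cycle, 5 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.28, adjusted p = 0.0278). Among these, Hpd of tyrosine breakdown rose by 0.82 ± 0.22 and Aass of lysine breakdown by 1.60 ± 0.49 in the authors' deposited table.

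Cholesterol synthesis genes had a median of -0.71 at 6 h (adjusted p = 0.000964). Of 24 tested, 0 rose and 6 fell (0 and 11 adjusted over the list alone). The synthase Hmgcs1 (-1.19 ± 0.19), the squalene synthase Fdft1 (-1.29 ± 0.28) and the mevalonate decarboxylase Mvd (-2.47 ± 0.56) fell in the authors' deposited table. Lipogenesis genes had a median of -0.76 (adjusted p = 0.000964) although 0 of 17 passed, over all genes or adjusted over the list alone. PPARA target genes went both ways, with 3 of 23 up and 3 down (5 and 4 adjusted over the list alone; median 0.14, adjusted p = 0.325). The lipid droplet protein Plin5 (1.38 ± 0.35) and the pyruvate dehydrogenase kinase Pdk4 (3.46 ± 0.99) rose and the pantetheinase Vnn1 (-1.08 ± 0.32) fell in the authors' deposited table. Of the 18 tested sphingolipid genes, 0 rose and 1 fell, also adjusted over the list alone; this was the ceramide synthase Cers6 (-1.58 ± 0.29 in the authors' deposited table).

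Beyond these lists, the genes with the largest changes at 6 h of at least 2 CPM included Moxd1 (6.95 ± 2.35), Fam107a (4.23 ± 1.07), the lipopolysaccharide co-receptor Cd14 (4.22 ± 0.93) and the ferritin receptor Scara5 (3.60 ± 0.94), which rose in the authors' deposited table. Cyp2a22 (-4.21 ± 0.82), Foxq1 (-3.65 ± 0.72), Nipal1 (-3.40 ± 0.82) and Tnfrsf19 (-3.38 ± 0.71) fell in the authors' deposited table. The cold-inducible RNA-binding protein gene Cirbp fell at 6 h (-0.96 ± 0.33, adjusted p = 0.0489), and Rbm3 had -0.49 ± 0.32 (adjusted p = 0.391) in the authors' deposited table. Markers of Kupffer cells, the macrophages of the liver, had a median of -0.39 at 6 h (adjusted p = 0.00439), with 0 of 12 passing over all genes or adjusted over the list alone. Endothelial markers had 0.11 (adjusted p = 0.586) and mitochondrially encoded transcripts 0.24 (adjusted p = 0.102). Stress response genes (median 0.43, adjusted p = 0.000964), insulin and FoxO-responsive genes (0.40, 0.00303), acute phase genes (0.31, 0.00729) and proliferation genes (0.35, 0.0342) also had medians above random lists at 6 h. Their members counted 0 up and 2 down of 16 (5 and 2 adjusted over the list alone), 1 and 0 of 14 (6 and 2), 1 and 0 of 19 (1 and 0) and 1 and 0 of 11 (2 and 0). Calls at 6 h were lost with the mean fold change for clock, stress response, proliferation and Kupffer cell genes, with the mean Wald statistic for clock, stress response, insulin and FoxO-responsive, acute phase and proliferation genes, and with genes of at least 2 CPM alone for proliferation genes. At 6 h 13 of 34 testable lists stood apart from random lists, 8 above 0 and 5 below. These list tests treat genes as independent, so their p-values are too small where members vary together between libraries.

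At 12 h the clock repressor Nfil3 rose again and few other genes passed. In the authors' deposited table for 12 h, 18 of 14618 genes changed, 8 up and 10 down, of which 12 changed at least 2-fold. The cytoskeletal adaptor Hip1r (1.37 ± 0.29), Nfil3 (1.45 ± 0.35), the glycolytic aldolase Aldoa (0.85 ± 0.20), Adnp2 (0.78 ± 0.18), Arhgap32 (0.77 ± 0.18) and Zfp592 (0.49 ± 0.11) rose in the authors' deposited table. The cytochrome Cyp2a22 (-3.39 ± 0.81), Phlda1 (-3.15 ± 0.67), the calcineurin regulator Rcan2 (-1.21 ± 0.30), the creatine transporter Slc16a12 (-1.10 ± 0.25) and the D-glutamate cyclase Dglucy (-0.72 ± 0.15) fell in the same authors' deposited table. Those are all the genes past the threshold that have a settled symbol and at least 2 CPM.

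Single genes of the study's question did not pass at 12 h. Hnf4a had 0.41 ± 0.13 (adjusted p = 0.212), Elovl3 0.63 ± 0.42 (adjusted p = 0.662) and Pex11a 0.10 ± 0.27 (adjusted p = 0.958) in the authors' deposited table. Medians of the peroxins (-0.04, adjusted p = 0.586), the other peroxisomal genes (-0.07, adjusted p = 0.231) and the elongation genes (-0.00, adjusted p = 0.963) did not stand apart from random lists.

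Whole lists nevertheless stood apart at 12 h: 16 of 36 did, 13 above 0 and 3 below. Glucocorticoid-responsive genes (median 0.68), immediate early genes (0.90), acute phase genes (0.51), PPARA targets (0.39), amino acid breakdown genes (0.32) and male-biased genes (0.32) lay above random lists, each at an adjusted p of 0.000964. Over all genes, 0 members of these 6 lists passed. Adjusted over the list alone, 2 glucocorticoid-responsive genes, 1 PPARA target and 2 amino acid genes rose and 1 immediate early gene and 1 male-biased gene fell. Cholesterol synthesis (-0.39) and lipogenesis (-0.57) lay below, each at 0.000964, as did the 5 tested female-biased genes (-1.75, adjusted p = 0.000964), of which too few had at least 2 CPM for a test. Gluconeogenesis (0.26, adjusted p = 0.0124), heat shock (0.31, 0.00236), stress response (0.30, 0.00163), insulin and FoxO-responsive (0.24, 0.0112) and interferon genes (0.29, 0.0156) lay above random lists as well. Hepatocyte markers had a median of 0.30 (adjusted p = 0.00163) and mitochondrially encoded transcripts 0.23 (adjusted p = 0.00835). Calls at 12 h were lost with the mean fold change for male-biased, stress response, mitochondrially encoded and hepatocyte genes, and with the mean Wald statistic for PPARA targets and male-biased, gluconeogenesis, interferon and mitochondrially encoded genes. With random lists not matched on expression the calls for insulin and FoxO-responsive and gluconeogenesis genes were lost, and with random lists of protein-coding symbols the mitochondrially encoded list had too few members to test.

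The low count at 12 h did not go with a larger error. The authors' SE at 12 h was, at the median gene of at least 2 CPM, 1.00 times that at 6 h and 0.998 times that at 24 h. An unadjusted p under 0.05 was reached by 1675 genes (6.35%) at 12 h, against 3146 (11.9%) at 6 h and 4010 (15.2%) at 24 h, of 26380 with a p. A share of about 0.05 is reached where no gene changes, so the 12 h count is not far above that.

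At 24 h the medians of gluconeogenesis genes and PPARA targets lay above random lists, whereas those of cholesterol synthesis genes, interferon and inflammatory genes, xenobiotic cytochromes and Kupffer cell markers lay below. In the authors' deposited table for 24 h, 1815 of 14618 genes changed, 935 up and 880 down. A change of at least 2-fold was seen for 653, 233 up and 420 down.

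**Figure D2:**
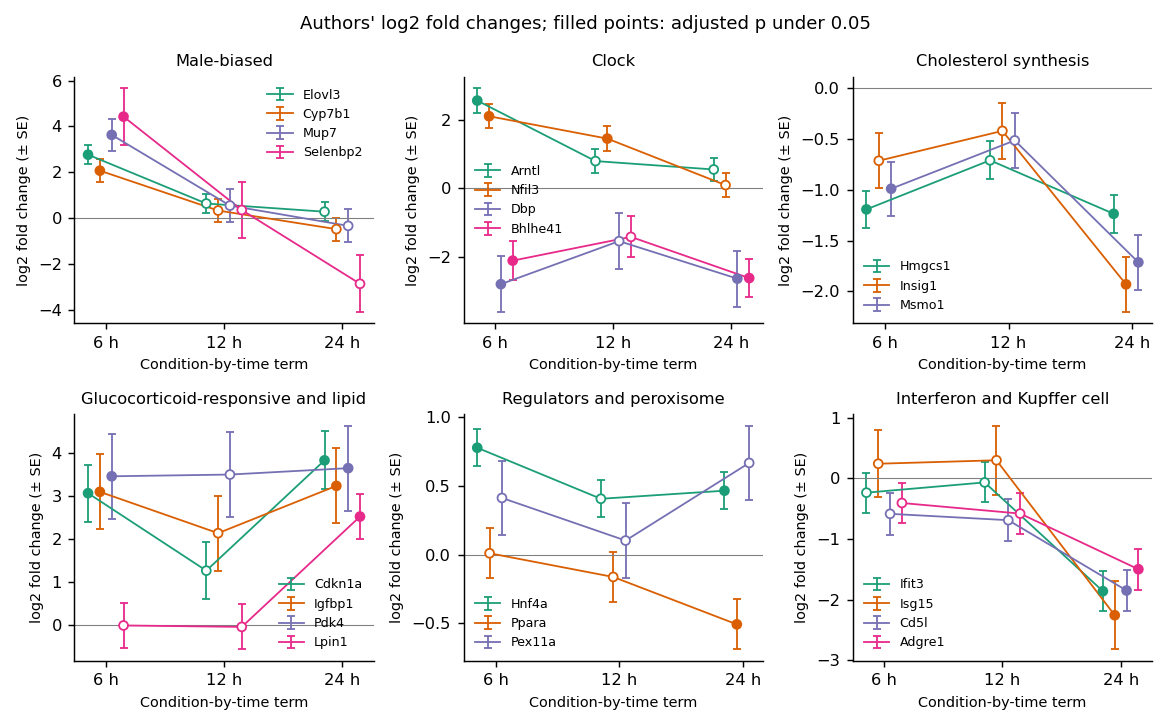
The authors' log2 fold changes (vertical axes, ± the authors' SE) of 22 genes in 6 groups for the terms at 6, 12 and 24 h (horizontal axes). Filled points passed an adjusted p of 0.05, open points did not. Elovl3 goes from 2.77 at 6 h to 0.27 at 24 h, and Lpin1 from -0.01 to 2.52.

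Hnf4a rose at 24 h by 0.46 ± 0.13 (adjusted p = 0.00937), and Ppara, the receptor for fatty acids, fell by 0.51 (SE 0.18, adjusted p = 0.0465) in the authors' deposited table. The Hnf4a term was positive at every time, which a difference between the cold and room temperature groups at 0 h could also give. How much of the Hnf4a term comes from the 0 h groups was not tested. Of 17 tested liver transcription factors, 2 rose and 5 fell, also adjusted over the list alone (median -0.34, adjusted p = 0.0115). Cebpa (-1.23 ± 0.25), Foxa1 (-1.13 ± 0.24) and Nr5a2 (-0.56 ± 0.16) fell and the bile acid receptor Nr1h4 rose (0.46 ± 0.13) in the authors' deposited table. The list's call was lost with the mean Wald statistic and with random lists not matched on expression. Of 25 known HNF4A targets, 5 rose and 5 fell (6 and 6 adjusted over the list alone), and the median (-0.02, adjusted p = 0.728) and mean (0.17) differ in sign. The apolipoprotein gene Apoa4 (2.97 ± 0.51), the lipid transfer protein gene Mttp (0.93 ± 0.17), the phosphatidate phosphatase gene Lpin1 (2.52 ± 0.53) and the iron regulator Hamp (1.57 ± 0.34) were the 4 with the smallest adjusted p, all risen, in the authors' deposited table.

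Peroxisomal genes gave a few rises at 24 h and no shift of the whole list. Of 16 peroxins, 2 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.309). Pex13 rose (0.40 ± 0.14), and Pex11a had 0.67 ± 0.27 (adjusted p = 0.085), in the authors' deposited table. Of 26 peroxisomal beta-oxidation and matrix genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone; median 0.04, adjusted p = 0.987). Ehhadh (1.27 ± 0.45) and Hsd17b4 (0.38 ± 0.12), enzymes of peroxisomal beta-oxidation, rose and catalase, Cat, fell (-0.74 ± 0.14) in the authors' deposited table. Of 12 tested elongation genes, 0 rose and 0 fell at 24 h, over all genes or adjusted over the list alone (median 0.04, adjusted p = 0.869). Elovl3 had 0.27 ± 0.42 in the authors' deposited table (adjusted p = 0.737).

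PPARA targets had a median of 0.66 at 24 h (adjusted p = 0.000964), with 9 of 23 up and 0 down (11 and 1 adjusted over the list alone). The lipid droplet proteins Plin2 (1.52 ± 0.36) and Plin5 (1.37 ± 0.35) and the kinase Pdk4 (3.65 ± 0.99) rose in the authors' deposited table. The hormone gene Fgf21 rose by 1.62 ± 0.59 (adjusted p = 0.0492), and the carnitine palmitoyltransferase Cpt1a had 0.25 ± 0.16 (adjusted p = 0.324) in the authors' deposited table. Gluconeogenesis genes had a median of 0.76 (adjusted p = 0.000964), with 5 of 11 up and 0 down, also adjusted over the list alone. The aminotransferases Got1 (1.87 ± 0.34), Gpt2 (1.06 ± 0.23) and Tat (1.71 ± 0.41) and the glucose-6-phosphatase G6pc (1.40 ± 0.34) rose in the authors' deposited table. Of 18 amino acid and urea cycle genes, 7 rose and 1 fell (7 and 3 adjusted over the list alone; median 0.07, adjusted p = 0.869). Arg1 (1.43 ± 0.26) and Asl (1.15 ± 0.21) of the urea cycle rose and Otc (-0.72 ± 0.16) of the same cycle fell in the authors' deposited table. Of 16 triglyceride genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.22, adjusted p = 0.123). Here Lpin1, Mttp and the lipase gene Pnpla2 (1.42 ± 0.30) rose and the hepatic lipase gene Lipc (-0.94 ± 0.17) fell in the authors' deposited table.

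Glucocorticoid-responsive genes had a median of 1.00 at 24 h (adjusted p = 0.000964), with 7 of 15 up and 0 down (8 and 1 adjusted over the list alone). Fkbp5 (1.74 ± 0.28), Cdkn1a (3.83 ± 0.67) and Ddit4 (2.91 ± 0.73) rose in the authors' deposited table. Immediate early genes had a median of 0.91 (adjusted p = 0.000964), with 3 of 13 up and 0 down, also adjusted over the list alone. Jun (1.88 ± 0.49), Klf6 (1.26 ± 0.34) and Atf3 (2.02 ± 0.60) rose in the authors' deposited table. Heat shock genes had a median of 0.36 (adjusted p = 0.0207), with 5 of 13 up and 0 down, also adjusted over the list alone, among them Hspa8 (1.03 ± 0.23 in the authors' deposited table). Glucocorticoid-responsive and heat shock genes lay above random lists at all 3 times, which a difference between the 0 h groups could also give. The glucocorticoid-responsive median change from 6 to 24 h was 0.05 (adjusted p = 0.703 against random lists), though those from 6 to 12 h and from 12 to 24 h passed. For heat shock genes no change between times passed. Acute phase genes also lay above random lists at all 3 times, and cholesterol synthesis and lipogenesis genes below, which a 0 h difference could give too. The acute phase change from 6 to 24 h (adjusted p = 0.253) and the lipogenesis change from 12 to 24 h (0.985) did not pass against random lists. The other changes of acute phase, cholesterol synthesis and lipogenesis genes between times passed. What share the 0 h groups hold in any of these lists was not tested. Rbm3 rose at 24 h by 1.15 ± 0.32 (adjusted p = 0.00567), and Cirbp had 0.71 ± 0.32 (adjusted p = 0.131) in the authors' deposited table; adjusted over the list alone, both rose.

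Cholesterol synthesis genes had a median of -1.24 at 24 h (adjusted p = 0.000964), with 0 of 24 up and 15 down (0 and 19 adjusted over the list alone). The sterol sensor Insig1 (-1.93 ± 0.27), Hmgcs1 (-1.24 ± 0.19), Msmo1 (-1.71 ± 0.27) and Nsdhl (-1.25 ± 0.25) fell in the authors' deposited table. Of 16 bile acid genes, 1 rose and 5 fell (2 and 6 adjusted over the list alone; median -0.42, adjusted p = 0.00565). The transporters Slco1a1 (-1.25 ± 0.24), Abcb11 (-0.98 ± 0.22) and Slco1b2 (-0.81 ± 0.19) and the reductase Akr1d1 (-1.30 ± 0.31) fell in the authors' deposited table. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.62 ± 1.11 (adjusted p = 0.782) in the authors' deposited table. Of 16 xenobiotic cytochromes and related genes, 1 rose and 6 fell (2 and 6 adjusted over the list alone; median -0.65, adjusted p = 0.00163). Cyp2c50 (-1.86 ± 0.21), Cyp2c29 (-1.87 ± 0.25), Cyp1a2 (-1.08 ± 0.20) and Cyp2c37 (-1.12 ± 0.25) fell in the authors' deposited table; the Cyp2c genes are near-identical and can share reads. Lipogenesis genes had a median of -0.38 (adjusted p = 0.00729), with 1 of 17 up and 1 down (1 and 2 adjusted over the list alone). The desaturase Scd2 (-0.94 ± 0.23) fell and the acetyl-CoA carboxylase Acacb (1.50 ± 0.45) rose in the authors' deposited table.

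Interferon and inflammatory genes had the lowest median of the tested lists at 24 h, -1.25 (adjusted p = 0.000964), with 0 of 12 up and 6 down (0 and 7 adjusted over the list alone). Ifit3 (-1.86 ± 0.33), Irf7 (-1.64 ± 0.33) and Ifit1 (-2.05 ± 0.49) fell in the authors' deposited table. Kupffer cell markers had a median of -0.83 (adjusted p = 0.000964), with 0 of 12 up and 8 down (0 and 10 adjusted over the list alone). Cd5l (-1.85 ± 0.35), Lyz2 (-1.52 ± 0.31), Vsig4 (-1.11 ± 0.24) and Adgre1 (-1.50 ± 0.34) fell in the authors' deposited table. Stellate cell and fibroblast markers had a median of -0.48 (adjusted p = 0.0132), with 0 of 11 up and 5 down (0 and 6 adjusted over the list alone), among them the collagens Col3a1 (-2.29 ± 0.45) and Col1a2 (-1.32 ± 0.36), Lrat (-1.08 ± 0.34) and Reln (-0.58 ± 0.15) in the authors' deposited table. Endothelial markers had a median of -0.11 (adjusted p = 0.348), with 1 of 11 up and 2 down (1 and 3 adjusted over the list alone). Lyve1 rose (1.39 ± 0.40) and Kdr (-0.38 ± 0.11) and Dnase1l3 (-0.50 ± 0.15) fell in the authors' deposited table. Hepatocyte markers had a median of 0.09 (adjusted p = 0.802) and mitochondrially encoded transcripts 0.18 (adjusted p = 0.307). Of 8 adipocyte markers 3 were tested, too few for a list test. Fabp4 rose at 6 h (1.64 ± 0.48) and at 24 h (2.02 ± 0.48), Car3 fell at 24 h (-3.92 ± 0.41) and Cfd had 1.38 ± 1.74 at 24 h (adjusted p = 0.666) in the authors' deposited tables; the other 5 had a mean normalized count of 1.99 or less and no adjusted p. Lymphocyte, neutrophil and exocrine pancreas markers were too few as well, with 3, 2 and 1 tested and 0 past the threshold at 24 h. The 1 tested pancreas marker, Cela1, rose at 6 h (1.40) and had -0.46 at 24 h in the authors' deposited tables.

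**Figure D3:**
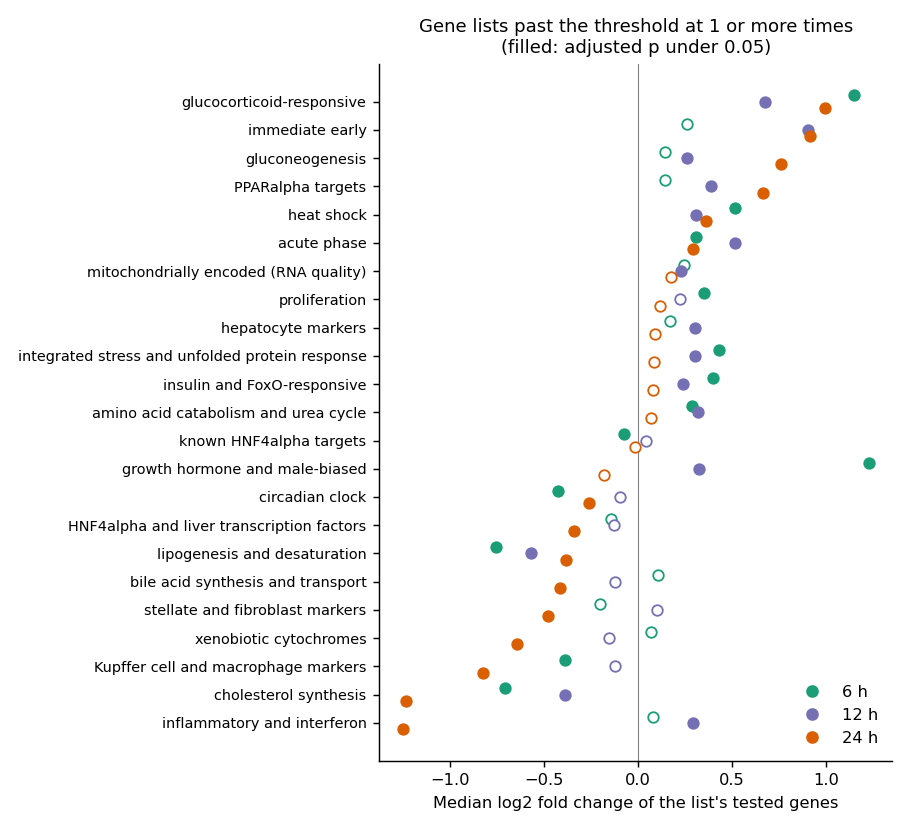
Median log2 fold change of the tested members (horizontal axis) of the 23 gene lists that were testable at all 3 times and stood apart from random lists at 1 or more of them (vertical axis, ordered by the 24 h median). Colours give the time, and filled points an adjusted p under 0.05. Male-biased genes go from 1.23 at 6 h to -0.18 at 24 h, and interferon genes from 0.08 to -1.25.

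Among the genes with the largest changes at 24 h of at least 2 CPM, Adcy1 (3.81 ± 0.98), the lipid droplet protein Cidec (3.25 ± 1.00), Igfbp1 (3.23 ± 0.87), the leptin receptor Lepr (3.11 ± 0.75), Scara5 (2.80 ± 0.95) and Zfp9 (2.65 ± 0.50) rose in the authors' deposited table. Clec2h (-6.88 ± 1.33), Phlda1 (-4.05 ± 0.68), the carbonic anhydrase Car3 (-3.92 ± 0.41), the guanylate-binding proteins Gbp10 (-3.94 ± 0.78) and Gbp11 (-3.33 ± 0.75) and the steroid enzymes Hsd3b2 (-3.34 ± 0.65) and Hsd17b6 (-3.17 ± 0.60) fell in the authors' deposited table. Hectd2os (-3.56 ± 0.43), Klhdc7a (-3.12 ± 0.75) and Serpina6 (-2.87 ± 0.38), which encodes the corticosteroid-binding globulin of plasma, fell as well in the authors' deposited table. Acute phase genes (median 0.29, adjusted p = 0.0269) also stood apart at 24 h, with 1 of 19 up and 0 down, as did clock genes (-0.26, 0.0335), with 0 of 18 up and 2 down, and cholangiocyte markers (-1.01, 0.019), with 0 of 5 up and 2 down. Adjusted over the list alone these were 1 and 0, 0 and 3, and 0 and 2; the mean of the acute phase genes (-0.02) had the opposite sign. Calls at 24 h were lost with the mean fold change for lipogenesis and acute phase genes, and with the mean Wald statistic for lipogenesis, bile acid, clock, acute phase and cholangiocyte genes. The clock call was also lost with random lists not matched on expression, and with genes of at least 2 CPM alone too few cholangiocyte markers were left to test. Mitochondrial fatty acid oxidation (median 0.25, adjusted p = 0.0675), ketone body synthesis (0.13, 0.794), sphingolipid (-0.09, 0.289), hepatokine (0.05, 0.869), oxidative phosphorylation (0.05, 0.987), proliferation (0.11, 0.371) and erythroid genes (0.00, 0.936) did not stand apart at 24 h. At 24 h 16 of 36 testable lists stood apart from random lists, 6 above 0 and 10 below.

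The terms were then compared between times, which asks whether the cold effect itself differed, since a 0 h difference enters all 3 terms alike and drops out. The male-biased Elovl3, Cyp7b1 and Mup7 had lower terms at 24 h than at 6 h, and Rbm3 and Cirbp higher ones. With the covariance of the 2 terms set to 0, which gives the largest standard error, 307 of 13084 genes differed between 6 and 24 h, 122 higher and 185 lower at 24 h. The same test gave 45 of 14618 genes between 12 and 24 h (18 higher and 27 lower at 24 h) and 2 of 13084 between 6 and 12 h. With a covariance of 0.5 of the mean variance, as the shared 0 h groups would give, the counts were 1831, 940 and 93. The change from 6 to 24 h was -2.49 ± 0.60 for Elovl3 (adjusted p = 0.00498), -2.56 ± 0.71 for Cyp7b1 (adjusted p = 0.0233) and -3.98 ± 1.01 for Mup7 (adjusted p = 0.00985). It was 1.65 ± 0.45 for Rbm3 (adjusted p = 0.0207) and 1.67 ± 0.46 for Cirbp (adjusted p = 0.0212). For Arntl it was -2.01 ± 0.50 (adjusted p = 0.00701), and for Car3 -3.91 ± 0.58 (adjusted p = 4.06e-08).

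Passing at both 6 and 24 h were 242 genes, of which 135 rose and 90 fell at both times and 17 changed in opposite directions. Independent lists of these sizes would share 36.0 risen and 26.8 fallen genes among 13084. Simulated unchanged groups with shared 0 h libraries shared 2.20 and 2.34, but these groups hold no changed genes. Their overlap therefore does not show what the shared 0 h libraries add to lists of the observed sizes. Across the genes tested at both times, the log2 fold changes correlated with Pearson's r = 0.482 and Spearman's rho = 0.461 between 6 and 24 h and with r = 0.688 and rho = 0.632 between 6 and 12 h (13084 genes each), and with r = 0.569 and rho = 0.489 between 12 and 24 h (14618 genes). Genes are not independent replicates, and the shared 0 h libraries alone gave r = 0.496, 0.503 and 0.493 in simulated unchanged groups. The covariance was 0.182 against a simulated 0.0598 between 6 and 24 h, 0.164 against 0.0602 between 6 and 12 h, and 0.217 against 0.0863 between 12 and 24 h. A split of the 0 h libraries could not be made without values per library, so part of the excess may come from them.

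**Figure D4:**
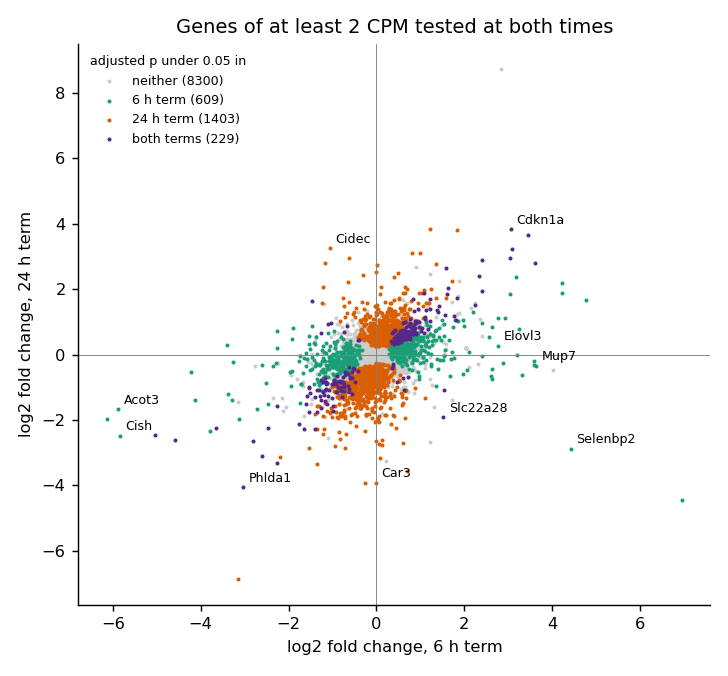
Log2 fold change at 24 h (vertical axis) against that at 6 h (horizontal axis) in the authors' deposited tables, 1 point for each of 10541 genes of at least 2 CPM tested at both times. Colours mark genes with an adjusted p under 0.05 at 6 h only (609), at 24 h only (1403), at both (229) or at neither (8300).

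A total of 5 genes passed in all 3 tables, each in 1 direction. Zfp592, Arhgap32 and the predicted gene 1700017B05Rik rose, and Phlda1 and the predicted gene Gm42796 fell; the predicted genes were named after their values were seen. Phlda1 (ENSMUSG00000020205) had -3.03 ± 0.67, -3.15 ± 0.67 and -4.05 ± 0.68 at 6, 12 and 24 h in the authors' deposited tables. A term of like size at all 3 times is also what a difference between the cold and room temperature groups at 0 h would give. At an unadjusted p under 0.05, 416 of 13084 genes moved 1 way in all 3 tables, 236 up and 180 down, against a mean of 42.0 and a highest of 60 in 100 simulations of unchanged groups.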

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

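All tests of explanations in this part, and the tests of list differences, were chosen after the values had been seen; the tests of genes between times were fixed before, except for the size of the covariance.

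The cold effect differed between times for 307 genes from 6 to 24 h, 45 from 12 to 24 h and 2 from 6 to 12 h. The last are Rfx5 (-1.66 at 6 h and -0.05 at 12 h) and Shld2 (1.12 and 0.09 in the authors' deposited tables), named after their values were seen. Of the 242 genes past the threshold at 6 and 24 h in the authors' deposited tables, 17 had opposite directions and also passed the test of the difference. Named after their values were seen, Ces3a (0.48 at 6 h, -0.83 at 24 h), Cyp1a2 (0.63 and -1.08) and the organic anion transporter Slc22a28 (1.52 and -1.91) turned from higher to lower, and Trim24 (-1.25 and 0.66) and the cholesterol ester hydrolase Nceh1 (-0.67 and 0.86) from lower to higher in the authors' deposited tables.

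Lists differed between times as follows. From 6 to 12 h, medians of the gene-wise change were positive for lipogenesis (0.19), PPARA targets (0.12), cholesterol synthesis (0.32), known HNF4A targets (0.10), clock genes (0.17), acute phase genes (0.17) and stellate cell markers (0.37). They were negative for bile acid genes (-0.22), glucocorticoid-responsive genes (-0.27) and male-biased genes (-0.86). From 12 to 24 h they were positive for mitochondrial fatty acid oxidation (0.26), PPARA targets (0.38), glucocorticoid-responsive genes (0.29) and female-biased genes (1.11). In the same step they were negative for cholesterol synthesis (-0.60), insulin and FoxO-responsive genes (-0.44), acute phase genes (-0.25), male-biased genes (-0.44), interferon genes (-1.52), Kupffer cell markers (-0.84) and stellate cell markers (-0.59). From 6 to 24 h they were positive for peroxins (0.24), peroxisomal enzymes (0.27), lipogenesis (0.44), PPARA targets (0.41) and triglyceride genes (0.24). Over that span they were negative for cholesterol synthesis (-0.35), male-biased genes (-1.57), interferon genes (-1.48) and Kupffer cell markers (-0.61). For the peroxisomal enzymes the list's own median was 0.10 at 6 h and 0.04 at 24 h, so it went the other way from the median gene-wise change. Each of these 30 of 104 tests passed at an adjusted p under 0.05 against random lists, which treat members as independent. Set against the members' own standard errors, the male-biased changes from 6 to 12 h and from 12 to 24 h were 5.27 and 2.68 of their standard error where members vary independently but 1.57 and 0.793 where they vary as one, and the clock change from 6 to 12 h had a p of 0.264 with independent members.

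Male-biased genes had a higher median term at 6 h than at 24 h. A difference between the 0 h groups as the whole cause is argued against by the median 6 h minus 24 h difference of 1.57, outside random lists (permutation p = 0.0002, the smallest they can give), since a 0 h difference would leave it near 0. It was 9.55 of its standard error from the members' own errors where they vary independently and 2.84 where they vary as one. Reads shared between near-identical Mup genes are argued against by the median of 0.848 at 6 h over the 12 members that are not Mup genes, of which 6 rose and 2 fell (permutation p = 0.0002 against random lists). A biological explanation that the design names, a cold effect on male liver expression at 6 h, stays open as a hypothesis. Collection of the cold and room temperature livers at different hours stays open too, since the labels give no clock hour. Growth hormone was not measured.

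Markers of Kupffer cells had a median below random lists at 24 h, and the most abundant, Clec4f (57.0 CPM, named after its values were seen) and Cd5l (42.2 CPM), both fell. This was not particular to Kupffer cells: stellate cell and fibroblast markers (median -0.48, adjusted p = 0.0132, 5 of 11 fell) and cholangiocyte markers (-1.01, adjusted p = 0.019, 2 of 5 fell) lay below random lists as well. A lower share of all non-hepatocyte cells would lower endothelial markers alike, but the endothelial median lay 0.715 above the Kupffer cell median (permutation p = 0.00052, two-sided, members permuted between the 2 lists). This permutation treats markers as independent and does not measure the spread between libraries, so its p is too small where markers vary together. A 0 h difference as the whole cause would leave the median change from 12 to 24 h near 0. It was -0.837, outside random lists (permutation p = 0.0002), and 5.78 of its standard error where members vary independently. Where they vary as one it was 1.98, and from 6 to 24 h these ratios were 4.27 and 1.45. These ratios took a covariance of 0 between the terms, which gives the largest standard error. The change from 12 to 24 h thus argues against a 0 h difference as the whole cause, though narrowly where members vary as one. The change from 6 to 24 h does so only where members vary less than as one. How members vary cannot be estimated without values per library, so a 0 h difference as part of the cause stays open. A lower share of several cell types other than endothelial cells, fewer Kupffer cells, or lower expression of these genes within them may each be the cause, and none of these was tested.

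Clock genes stood apart at 6 h as a list. Collection of cold and room temperature livers at different hours could move them as a cold effect on the clock would; the labels give no clock hour, so these cannot be told apart. The mean of Arntl, Clock, Npas2, Cry1 and Nfil3 minus that of Dbp, Tef, Per2, Per3, Nr1d1, Nr1d2, Bhlhe41 and Ciart was 2.87 at 6 h, but these 13 of the 18 tested members were named and grouped with their values at 6 h known and each group has 1 sign there, so a positive value there follows from the grouping and decides nothing. A difference between the 0 h groups also cannot be told apart: the mean 6 h minus 24 h difference was 1.81 of its largest possible standard error for the first 5 genes and -0.183 for the other 8. The list's median change from 6 to 12 h (0.17) passed against random lists, yet against the members' own standard errors, taken as independent, it had a two-sided p of 0.264. Arntl alone, tested first and then replaced by the 5 genes because it is their most changed member, had a ratio of 4.05; it and Nfil3, 2 of the 18 members, passed the test of the difference from 6 to 24 h, which bears on these genes alone.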

How the results depend on the processing

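Alternatives added after the data were seen were the covariance, the unfiltered adjustment, the genes tested in all 3 tables and the list without Mup genes. No paired analysis was possible because the tables hold no values per library; leaving out replicates, other splits of the samples and other normalizations were not run for the same reason, and depth per library is unknown. Thresholds of 0.01 and 0.1 gave 388 and 1478 genes at 6 h, 0 and 54 at 12 h, and 896 at 24 h (0.01). Benjamini-Yekutieli adjustment gave 270, 0 and 675 genes at 6, 12 and 24 h, and Bonferroni 105, 3 and 229. At 12 h the 0 stands beside 1675 genes (6.35% of those with a p) at an unadjusted p under 0.05 in the authors' DESeq2-style table. A log2 fold change of at least 1 gave 345 at 6 h and 653 at 24 h. Adjustment over every gene with a p gave 10 at 12 h. These counts move by construction. For differences between times, 6 to 12 h gave 0 (Benjamini-Yekutieli) and 93 (half-shared covariance). From 12 to 24 h the counts were 20 (0.01), 69 (0.1), 15 (Benjamini-Yekutieli), 15 (Bonferroni) and 940 (half-shared covariance). From 6 to 24 h they were 115 (0.01), 522 (0.1), 195 (fold minimum), 72 (Benjamini-Yekutieli), 43 (Bonferroni) and 1831 (half-shared covariance). Pearson's r became 0.839 (6 and 12 h), 0.813 (12 and 24 h) and 0.527 (6 and 24 h) over genes past the threshold at either time. Wald statistics gave 0.657, 0.501 and 0.424 in that order, and genes of at least 2 CPM 0.703 for 6 and 12 h and 0.437 for 6 and 24 h; the cause was not tested. The clock list at 6 h turned sign with the mean Wald statistic (0.0527), and the acute phase list at 24 h with the mean (-0.0205), since members go both ways. Of the 60 calls for genes with the largest changes and genes fixed beforehand, 26 were lost with Benjamini-Yekutieli, 36 with Bonferroni and 10 with the unfiltered adjustment. Of 267 values of the 45 list calls under the alternatives fixed before the data were examined, 234 kept direction and call, 31 missed the threshold and 2 turned sign, those above; 3 more gave no value because fewer than 5 members were left. Subtracting the median of all genes leaves the p as it was, so 45 of the 267 kept their call by construction.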

Other observations

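Gene families read from symbols, and the members named, were chosen after the values were seen, so these are descriptions; they hold members of at least 2 CPM with an adjusted p, and members below that level are not counted. At 24 h 9 of 20 proteasome regulatory subunits rose and 0 fell (median 0.31, adjusted p = 0.00707 against random lists), such as Psmd8 (0.98) and Psmd4 (0.79) in the authors' deposited table. Of 17 proteasome core subunits, 4 rose and 1 fell, and their median of 0.26 did not pass (adjusted p = 0.0597). Of 52 translation initiation factors and related genes, 12 rose and 3 fell (median 0.27, adjusted p = 0.00066), with Eif2b3 (1.32), Eif1a (1.00) and Eif4a1 (0.79) among the risen in the authors' deposited table. Cytosolic ribosomal proteins did not share this: 0 of 76 rose and 1 fell, with a median of -0.02 (adjusted p = 0.186). Their median lay below random lists at 6 h (-0.08, adjusted p = 0.00066) and at 12 h (-0.07, adjusted p = 0.0109), with 0 members past the threshold.

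Other families had medians below those of random lists at 24 h. Of 8 guanylate-binding proteins, which interferon induces, 0 rose and 6 fell (median -1.45, adjusted p = 0.00066). Of 12 carboxylesterases, 0 rose and 7 fell (median -0.66), with Ces1g at -1.44 and Ces3a at -0.83 in the authors' deposited table. Of 16 collagens, 1 rose and 7 fell (median -0.69): Col3a1 (-2.29) and Col5a3 (-1.59) fell and Col15a1 (1.04) rose in the authors' deposited table. Of 12 aldo-keto reductases, 0 rose and 5 fell (median -0.56), led by Akr1c6 (-2.04 in the authors' deposited table). Among UDP-glucuronosyltransferases 0 of 16 rose and 5 fell (median -0.44, adjusted p = 0.00275). Medians of guanylate-binding proteins (-0.44, adjusted p = 0.00305), carboxylesterases (-0.31, 0.0012), aldo-keto reductases (-0.40, 0.00066) and UDP-glucuronosyltransferases (-0.20, 0.00784) also lay below random lists at 12 h, with 0 members past the threshold. The collagens did not (-0.03, 0.673). Carboxylesterases lay below at 6 h as well (-0.15, 0.0316), with 1 member risen. At 6 h 9 of 17 major urinary protein genes rose and 0 fell (median 2.32, adjusted p = 0.00066). Their median lay above random lists at 12 h too (0.30, adjusted p = 0.00066) and below them at 24 h (-0.29, adjusted p = 0.0191), with 0 members past the threshold at either time. Random lists treat these near-identical genes as independent, so those p-values are too small where members vary together. Mup7, for example, had 0.54 ± 0.71 at 12 h and -0.34 ± 0.71 at 24 h in the authors' deposited tables, so a change of sign is not shown. Reads can be split between near-identical members in most of these families.

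The predicted genes Gm24924 and Gm26244, named after their values were seen, had equal values in every table, with a log2 fold change of 25.97 at 24 h, a size that a group without reads gives and that is no usable fold.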
